A study of Mus musculus with 2 samples.

How the data were processed

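RNA from sorted iNKT cells of epididymal adipose tissue and spleen was measured on 1 Affymetrix mouse gene array per tissue. Per the labels' protocols, spleen was minced and washed, while adipose tissue was minced and digested with type 2 collagenase for 20 min at 37 °C, and cells of about 50 mice were pooled. RNA was converted to sense-strand cDNA with the Ambion WT Expression Kit, per the labels' protocols. The deposited values are probe set intensities on a linear scale, made by the authors with Affymetrix Power Tools and RMA, per the submitters' processing notes. RMA corrects background, normalizes probes between arrays and summarises them per probe set. The versions, the settings and the set of arrays normalized together are not given in the sources used here. The linear scale was read from the values, which hold no negative number and reach 20403 units. The interquartile range of the log2 values was 2.11 in the adipose array and 2.64 in the spleen array, so the adipose array had the narrower spread of values.

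Log2 was taken of the deposited intensities, with no further scaling in the main results. Probe sets were named through the platform annotation, with symbols updated through Entrez identifiers, of which 99.6% matched the mouse gene table of assembly GRCm38.p6. Of 24922 probe sets, 21425 had 1 gene symbol, 1399 had several and were left unnamed, and 2098 were not listed in the annotation used here. They gave 19752 genes, and for the 921 genes with more than 1 probe set the probe set of the highest mean level was kept. In 343 genes with 2 probe sets past the filter, the median absolute disagreement of their log2 differences was 0.21 and the 95th percentile 1.80, with 14.6% at least 1 apart, so a single probe set can misstate a difference. Genes with a log2 intensity of at least 7 (128 units) in at least 1 array were kept (8559, of which 5730 reached it in both), and a 2-fold difference was the threshold for counts. The number of arrays limits the precision.

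Before the data were examined, 30 gene lists, the rule for named genes and the alternative settings were fixed. The rule named the 12 genes with the largest difference in each direction (predicted genes and small RNA genes left out), up to 4 members with the largest difference in each list, and 16 genes regardless of value. The median log2 difference of a list (adipose minus spleen) was set against 10000 random lists of the same size, drawn with replacement from 20 bins of mean level. A list was said to stand apart under the 2.5 or over the 97.5 percentile. By this range, about 5% of 26 lists with no difference would stand apart. Some genes are in several lists (Zbtb16 is in the identity and NKT2 lists), so the lists are not independent. Percentiles describe these arrays and are not p-values, since genes are not replicates.

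Gene span came from GRCm38.p6 and was used only as a property of the gene, for 8555 of the genes past the filter. After the data were seen, random lists matched in 10 bins of level and 5 of span, and a loess of the difference on log10 span, were added. That loess also shifts the differences as a whole, so it was repeated in 20 shuffles of the spans among genes. GC content and transcript length were not used here. The procedures were tested on simulated arrays of the same genes. With an assumed noise of SD 0.15 per array on the log2 scale, all 100 genes changed by 2 and 98% of 100 genes changed by 1.5 were recovered, and 2.5% of 200 random lists stood apart. The noise of these arrays could not be measured, so the simulation checks the code and gives no rate of false calls for the data. The alternatives were fold thresholds of 1.5 and 4, level filters of 6 and 8 or none, centring of each array on its median, loess of the difference on mean level, quantile normalization, the mean of a gene's probe sets, only genes with 1 probe set, an offset of 32 units before log2, values under the filter set to it, and random lists not matched on level. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.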

Results

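Invariant natural killer T (iNKT) cells are T lymphocytes that carry a semi-invariant T cell receptor and recognise lipids presented by CD1d. Their expression was measured in adipose tissue and in spleen of the same wild-type C57/B6 mice, aged 6 weeks. Cells of about 50 mice were pooled, sorted as CD1d tetramer-positive, TCR beta-positive, CD45-positive and CD19-negative, and sorted again to a purity over 97%. The data hold 1 array of epididymal adipose iNKT cells and 1 array of splenic iNKT cells. With 1 array per tissue there was no replicate error, so no difference below has a test or a replicate check, and each describes these 2 arrays. Both arrays gave a value for 24922 probe sets. The median intensity was 85.6 in the adipose array and 81.8 in the spleen array, and the upper quartile was 187 and 238. Of 19752 named genes, 8559 reached a log2 intensity of 7 (128 units) in at least 1 array, the level filter used throughout.

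The comparison asked which genes iNKT cells of adipose tissue expressed at other levels than splenic iNKT cells. Of the transcription factor genes named regardless of value, Zbtb16 and Gata3 were at least 2-fold higher in the spleen array and Nfil3 in the adipose array. Zbtb16, which encodes PLZF, the factor that directs iNKT cell development (probe set 10593225), was 7.95-fold higher in the spleen array, at 2408 units against 303 in the adipose array (log2 difference -2.99, and -2.17 with the trend on gene span described below removed). Gata3, a factor of type 2 cytokine production, was 3.44-fold higher in the spleen array. Nfil3, which encodes the basic leucine zipper factor E4BP4 (probe set 10409278), was 3.60-fold higher in the adipose array, at 333 against 92.6 units. With values under the filter set to it, the log2 difference of Nfil3 was 1.38 in place of 1.85. Tbx21, which encodes T-bet, read 3414 units in the adipose array and 2499 in the spleen array, a 1.37-fold difference. Foxp3 and Pparg lay under the filter in both arrays. Rorc was not analysed here, since no probe set listed it as its single gene.

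Across genes, 472 were at least 2-fold higher in the adipose array and 2312 at least 2-fold higher in the spleen array, together 32.5% of the genes past the filter. The genes furthest higher in the adipose array included Ly6a2 (16.7-fold), the AP-1 subunits Fosb (13.4-fold) and Fos (12.4-fold), and the phosphatase gene Dusp1 (11.5-fold). They also included Il2 (9.45-fold), the nuclear receptors Nr4a1 (8.67-fold) and Nr4a2 (8.58-fold), and the calcium-binding protein gene S100a6 (7.82-fold). Stk32c (12.8-fold), the histone gene H2ac4 (7.70-fold), Tsc22d3 (7.58-fold), which encodes the glucocorticoid-induced protein GILZ, and Ppp1r15a (7.56-fold) completed the 12. Ly6a2 and H2ac4 belong to families of similar genes and are uncertain. At the other end, Ccr9, a chemokine receptor of gut homing, was 42.7-fold higher in the spleen array, and Il7r, the interleukin-7 receptor alpha chain, 27.1-fold. Ifi209 (16.9-fold), the phosphodiesterase gene Pde3b (13.9-fold), Cops2 (13.2-fold), Themis (12.9-fold) and Wwp1 (11.9-fold) followed. Ppp4r3b (11.7-fold), the interferon-induced gene Ifit1 (11.1-fold), Septin7 (10.97-fold), Cd96 (10.9-fold) and Rps6ka3 (10.8-fold) were the remaining genes of the 12. In 7 of the 12 genes highest in the adipose array and 9 of the 12 highest in the spleen array, the lower array was under the filter, so these folds rest on a weak signal. With such values set to the filter, the log2 difference was 1.77 in place of 3.24 for Il2 and -3.68 in place of -5.42 for Ccr9.

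**Figure D1:**
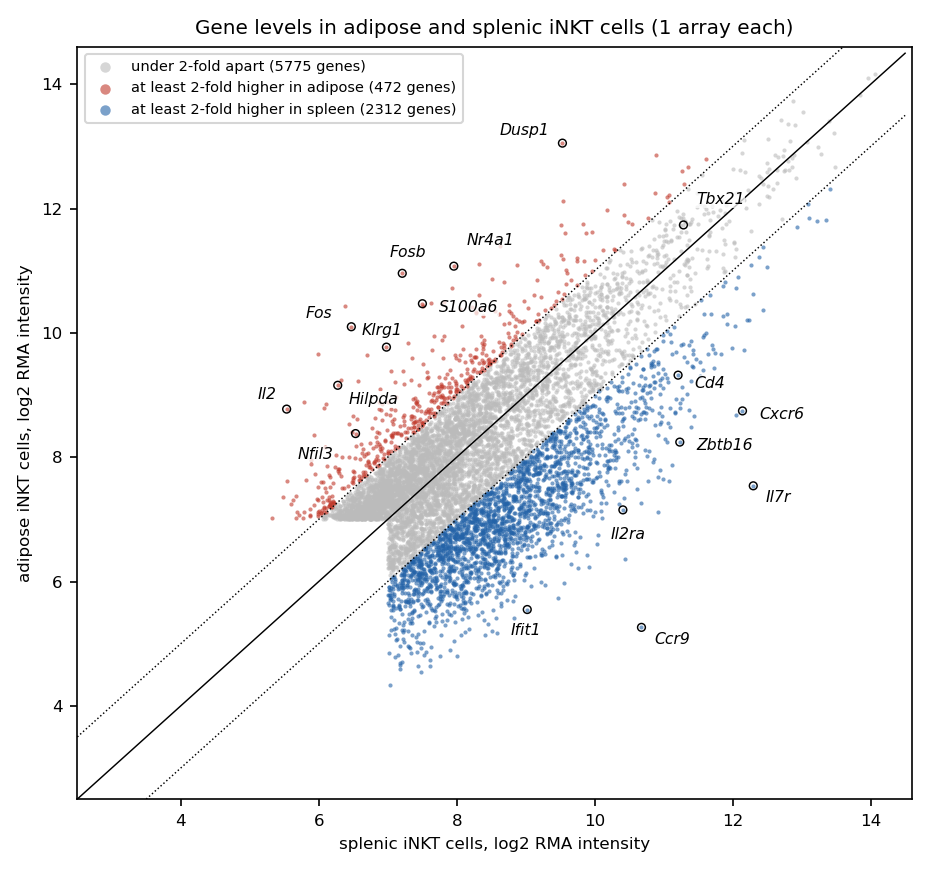
Log2 RMA intensity of each gene past the level filter in splenic iNKT cells (horizontal axis) and adipose iNKT cells (vertical axis), 1 array each, with lines at equal levels (solid) and at 2-fold differences (dotted). More genes lie at least 2-fold higher in the spleen array (2312, blue) than in the adipose array (472, red), and Dusp1, Fosb, Fos and Il2 lie far above the lines while Ccr9, Il7r and Cxcr6 lie far below.

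The excess on the spleen side went with gene span, the genomic distance from a gene's start to its end in the mouse assembly GRCm38.p6. The genes were split by span into 5 groups of 1711. In the group of the shortest spans (0.053 to 6.68 kb), the median log2 difference (adipose minus spleen) was 0.52, with 247 genes at least 2-fold higher in the adipose array and 79 in the spleen array. In the group of the longest spans (60.1 to 1998 kb) it was -0.94, with 22 and 813 genes. Spearman's rho between difference and span was -0.48 across 8555 genes, which are not independent replicates. With this trend removed by loess, a setting chosen after the data were seen, 952 genes were at least 2-fold higher in the adipose array and 1407 in the spleen array. Of these, 256 and 1298 were in the counts as deposited. Quantile normalization of the arrays gave 1151 and 1803 genes and moved the median difference of the genes past the filter from -0.10 to 0.27. Over all named genes the median was 0.20 as deposited, 0.13 after quantile normalization and 0.01 after loess on level. The adipose-higher share of the 2-fold genes was 17.0% as deposited, 39.0% after quantile normalization and 40.4% with the span trend removed. The same removal with spans shuffled among genes gave 1109 and 1792 genes and a share of 38.2% (means of 20 shuffles), so the rise in share did not need the true spans. It came with an upward shift of the differences, as the median of the genes past the filter went from -0.10 to 0.17 in the shuffles. Centring each array on its median did not raise the share, with 414 and 2407 genes and 14.7%. Because of the trend on span, each gene list below is set against random lists matched on level, and also against lists matched on level and span. Only the medians are compared so, and the counts of members are not. As 472 of all 8559 genes past the filter were in the adipose-higher count and 2312 in the spleen-higher count, an even split within a list is not the split of all genes.

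**Figure D2:**
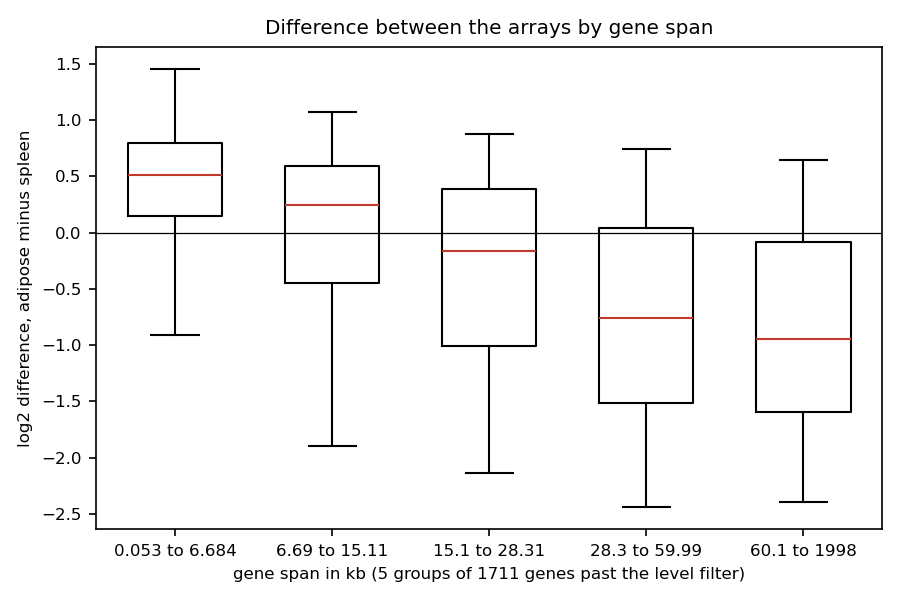
Log2 difference between the adipose and spleen arrays (vertical axis) in 5 groups of 1711 genes past the level filter, by gene span in kb (horizontal axis), with the median in red, boxes over the quartiles and whiskers from the 5th to the 95th percentile of genes. The median goes from 0.52 in the group of the shortest spans through 0.25, -0.16 and -0.75 to -0.94 in that of the longest.

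Immediate-early genes, which respond within minutes to receptor signals or to handling of cells, had the highest median difference of the fixed lists. Of 31 members past the filter, 19 were at least 2-fold higher in the adipose array and none in the spleen array. The median log2 difference of 1.32 exceeded all 10000 random lists of the same size, whether matched on level or on level and span, and was 0.87 with the span trend removed. Fosb, Fos, Dusp1 and Nr4a1 led it. Adipose tissue alone was digested with collagenase (20 min at 37 °C, per the labels' protocols), so digestion and tissue fall on the same array. Heat-shock genes went the other way. Of 12 members, 8 were at least 2-fold higher in the spleen array and none in the adipose array, with a median of -1.53 (percentile 0.09 on level, 0 on level and span). With only genes of 1 probe set it was -1.31, inside the range of random lists (percentile 2.6), a setting that leaves out Hsp90aa1, Dnaja1 and Hspd1 among other members. Chordc1 was 5.04-fold, Hsp90aa1 3.58-fold, Dnaja1 3.55-fold and Hspd1 3.49-fold higher in the spleen array.

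Cytokine genes were split. Il2, the T cell growth factor (probe set 10497878), read 438 units in the adipose array and 46.4 in the spleen array. The chemokine Ccl3 was 6.74-fold, Tnf 5.12-fold and Ccl1 3.14-fold higher in the adipose array, although Ccl3 and Ccl1 were under the filter in the spleen array. With values under the filter set to it, the log2 difference was 1.85 in place of 2.75 for Ccl3 and 0.24 in place of 1.65 for Ccl1. Il4 was 2.18-fold higher in the spleen array, and its log2 difference was -0.78 after quantile normalization in place of -1.13. Ifng read 1255 units in the adipose array and 937 in the spleen array. Il10, Il13 and Il17a lay under the filter in both arrays. In the cytokine and chemokine list, 5 of 15 members were at least 2-fold higher in the adipose array and 1 in the spleen array, with a median of 0.41 inside the range of random lists (percentile 94.8 on level, 61.2 on level and span).

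Regulatory and inhibitory-receptor genes also went both ways, with 5 of 18 members at least 2-fold higher in the adipose array and 6 in the spleen array. Over all 8559 genes past the filter these counts were 472 and 2312. Klrg1, an inhibitory receptor, was 6.91-fold higher in the adipose array. Il2ra, the interleukin-2 receptor alpha chain, was 9.56-fold and Ikzf2, which encodes Helios, 5.14-fold higher in the spleen array. The list's median was -0.59 (percentile 11.8 on level, 17.8 on level and span) and 0.26 with the span trend removed. Genes that dampen T cell receptor signals had a median of -0.03 (percentile 51.9), with 5 of 23 members at least 2-fold higher in the adipose array and 6 in the spleen array. The median was 0.27 after quantile normalization and 0.06 with the span trend removed, where 9 and 4 members, and 6 and 1, were at least 2-fold higher in the adipose and spleen arrays. Within that list the cytokine-signal suppressors Socs3 (4.51-fold) and Cish (4.17-fold) were higher in the adipose array, and the ubiquitin ligase gene Itch (3.77-fold, -0.99 on the log2 scale with the span trend removed) was higher in the spleen array.

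Lists of iNKT subset and natural killer (NK) receptor genes had medians on the spleen side, with members on both sides. The NK receptor list had a median of -1.80 (percentile 0.07 on level, 0.01 on level and span), with 7 of 11 members at least 2-fold higher in the spleen array and 2 in the adipose array. Cd226 was 5.88-fold, Klrd1 4.40-fold and Klrb1c, which encodes NK1.1, 3.48-fold higher in the spleen array. Klra3 (4.56-fold, adipose array under the filter) belongs to a family with near-identical copies and is uncertain. The NKT2 list had 10 of 13 members at least 2-fold higher in the spleen array and 1 in the adipose array, with a median of -1.13 (percentile 1.5 on level, 1.3 on level and span). The spleen-higher count was 6 of 14 after quantile normalization and 7 of 13 with the span trend removed. The list included Ccr9, Slamf6 (9.86-fold), Zbtb16 and the interleukin-25 receptor gene Il17rb (5.29-fold). In the NKT17 list, 5 of 8 members were at least 2-fold higher in the spleen array and 2 in the adipose array, with a median of -1.62 (percentile 0.24 on level, 0.11 on level and span). Its leading members on the spleen side were Il7r, the chemokine receptor Cxcr6 (10.5-fold), Rora (5.31-fold) and Maf (3.12-fold), none of them confined to this subset. The 2 members higher in the adipose array were Tmem176a (2.97-fold, spleen array under the filter) and Tmem176b (2.92-fold). Il17a, Il17f, Il23r and Ccr6 lay under the filter in both arrays, so the median does not cover them. With the level filter at 6, the NKT17 median was -0.085 (percentile 20.3).

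The NKT1 list had 7 of 19 members at least 2-fold higher in the spleen array and none in the adipose array. Its median of -0.38 lay inside the range of random lists matched on level (percentile 11.7) and at the 2.47 percentile when span was matched too. Slamf7 (6.70-fold), Stat4 (4.96-fold) and the receptor gene Cd160 (4.84-fold) were higher in the spleen array. Other members read higher in the adipose array by under 2-fold, among them Nkg7 (log2 difference 0.60), Tbx21 (0.45), Ifng (0.42) and Cxcr3 (0.37). With the span trend removed, Nkg7 (-0.03) and Cxcr3 (-0.13) no longer did. Of 21 T cell and iNKT identity genes, 9 were at least 2-fold higher in the spleen array and none in the adipose array. Their median was -0.62, at the 2.18 percentile on level, 4.95 on level and span, and -0.16 with the span trend removed. Slamf6, Zbtb16, Cd4 (3.70-fold) and Cd28 (2.94-fold) were higher in the spleen array. The receptor chains Cd3e and Cd3d, chosen after their values were seen, differed by -0.05 and -0.06, and by 0.09 and 0.20 after quantile normalization. The chain Cd3g, chosen in the same way, was 2.25-fold higher in the spleen array (-1.17, and -1.07 after quantile normalization).

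**Figure D3:**
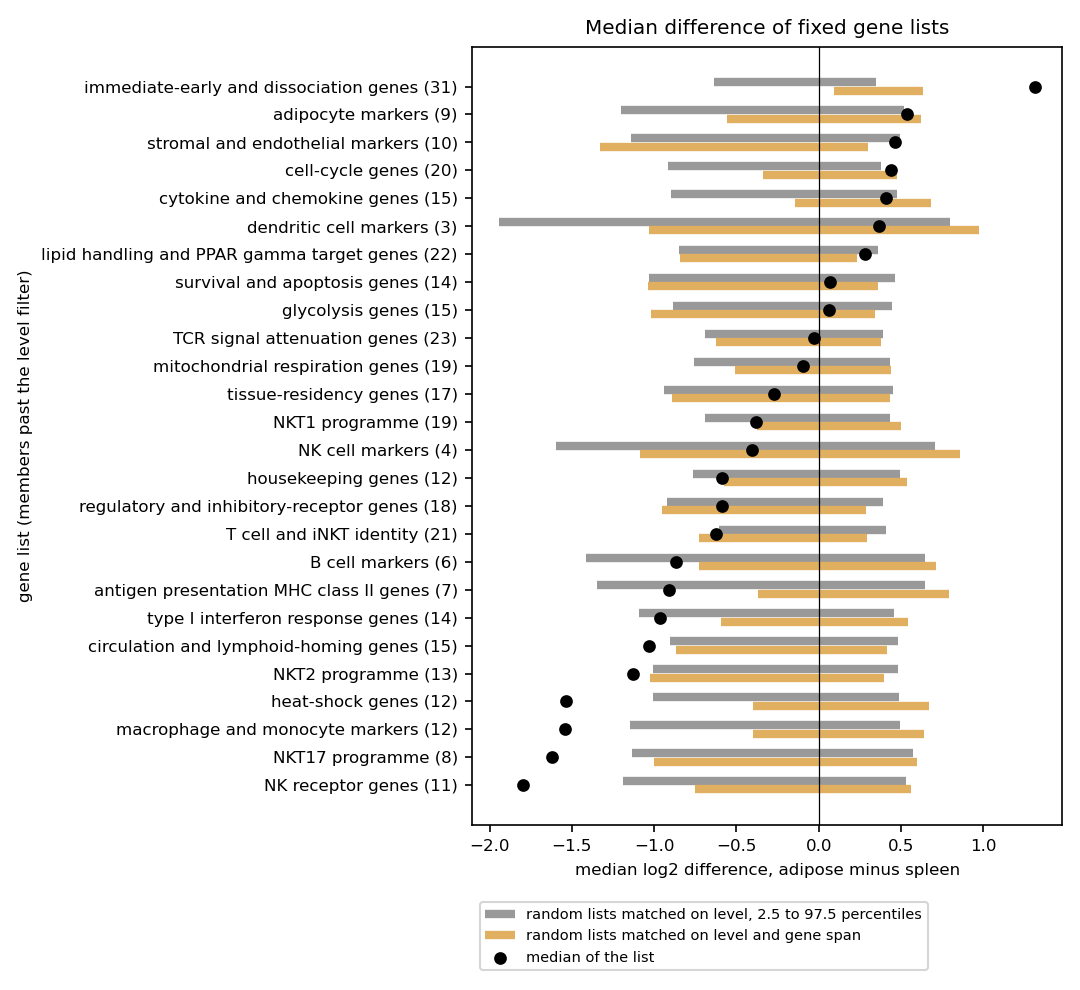
Median log2 difference between the adipose and spleen arrays (horizontal axis, black points) of 26 gene lists fixed before the data were examined (vertical axis, with the members past the level filter in brackets), with the range that is left without the outer 2.5% on each side of 10000 random lists matched on level (grey) or on level and gene span (orange). The immediate-early list (1.32) lies above both ranges, and the NK receptor (-1.80), NKT17 (-1.62), macrophage (-1.54), heat-shock (-1.53), NKT2 (-1.13) and circulation (-1.03) lists lie below both.

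The list of circulation and lymphoid-homing genes had a median on the spleen side as deposited, with members on both sides. Of 15 members, 8 were at least 2-fold higher in the spleen array and 1 in the adipose array (S1pr4, 2.89-fold), with a median of -1.03 (percentile 1.3 on level, 1.1 on level and span). Klf2 (log2 difference 0.89) and Itgb7 (0.80) were among the other members that read higher in the adipose array. Il7r, Klf3 (5.00-fold), Cmah (4.32-fold) and S1pr1 (3.91-fold), the receptor for lymphoid egress, led this list as deposited. Cmah and S1pr1 were under the filter in the adipose array, and differed by -1.34 and -1.37 with such values set to it. With the level filter at 8 the list lay inside the range of random lists (-1.09, percentile 6.3). With the span trend removed its median was -0.12, at the 22.4 percentile, and 5 members were at least 2-fold higher in the spleen array, as after quantile normalization, which also put 4 in the adipose array. Tissue-residency genes did not stand apart, with a median of -0.27 (percentile 34.8) that was 0.06 after quantile normalization and 0.23 with the span trend removed. Of 17 members, 5 were at least 2-fold higher in the adipose array, Nr4a1 among them, and 4 in the spleen array, among them Cxcr6, Icos (5.01-fold) and Inpp4b (4.70-fold).

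Type I interferon response genes had 7 of 14 members at least 2-fold higher in the spleen array and none in the adipose array. The median was -0.96, inside the range of lists matched on level (percentile 4.85) and below that of lists matched on level and span (percentile 0.20). Ifit1, Ifit3 (5.46-fold), Rtp4 (4.30-fold) and Ifit2 (3.82-fold) were higher in the spleen array, all under the filter in the adipose array. With such values set to the filter they differed by -2.02, -1.56, -1.94 and -0.35. Macrophage, B cell and MHC class II markers, given below, had negative medians too (-1.54, -0.87 and -0.91). The B cell and MHC class II lists lay inside the range of lists matched on level, and below that of lists matched on level and span. Among MHC class II genes, H2-DMa was higher in the adipose array (log2 difference 0.80). In the list of lipid handling and PPAR gamma targets, Hilpda, which encodes a lipid droplet protein, was 7.37-fold higher in the adipose array (log2 difference 2.16 with values under the filter set to it). The fatty-acid genes Scd2 (4.60-fold) and Acsl4 (4.35-fold, -1.31 on the log2 scale with values under the filter set to it) and the cholesterol exporter gene Abca1 (4.19-fold) were higher in the spleen array. Of its 22 members, 4 were at least 2-fold higher in the adipose array and 8 in the spleen array, against 5 and 4 after quantile normalization and 4 and 3 with the span trend removed. The median of 0.28 (percentile 93.9 on level, 98.6 on level and span) and the mean of -0.13 differed in sign.

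Cell-cycle genes had 5 of 20 members at least 2-fold higher in the adipose array, among them Plk1 (3.20-fold), Cdk1 (2.49-fold) and Ube2c (2.41-fold), and 2 in the spleen array, with Mcm4 at 3.34-fold. After quantile normalization these counts were 9 and 1 of 21, and with the span trend removed 4 and 2, without Ube2c (0.80). Their median was 0.44 (percentile 98.9 on level, 95.5 on level and span) and 0.21 with the level trend removed by loess (percentile 90.27). Glycolysis genes had a median of 0.06 (percentile 65.0), with Tpi1 2.10-fold higher in the adipose array and Pdk1 2.15-fold higher in the spleen array, the only members at least 2-fold apart of 15. Pdk1 differed by -0.80 after quantile normalization and -0.52 with the span trend removed, where Tpi1 differed by 0.64 and Slc2a1 (1.26) was the only member at least 2-fold apart. Mitochondrial respiration genes had a median of -0.09 (percentile 42.5). Sdha (3.08-fold), Ndufs1 (2.72-fold), Idh3a (2.64-fold) and Uqcrc2 (2.57-fold) were the 4 of 19 at least 2-fold higher in the spleen array, and none was in the adipose array. With the span trend removed 2 were, without Ndufs1 (-0.81) and Uqcrc2 (-0.95), and Ndufs1 differed by -0.55 with values under the filter set to it. After quantile normalization 3 members were at least 2-fold higher in the adipose array and 4 in the spleen array. Survival genes had a median of 0.07 (percentile 71.4) that was -0.70 with the level filter at 8. Of 14 members, 6 were at least 2-fold higher in the spleen array, led by Casp8 (4.67-fold), Cflar (3.09-fold) and Bcl2 (2.92-fold), and 2 in the adipose array, against 6 and 6 after quantile normalization and 2 and 3 with the span trend removed, without Cflar (-0.82) and Bcl2 (-0.72).

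Markers of other cells that the sort could hold were read the same way. Macrophage and monocyte markers were higher in the spleen array, with 8 of 12 members at least 2-fold higher there and a median of -1.54 (percentile 0.16 on level, 0.01 on level and span). With the level filter at 8 the median was again -1.54, at percentile 10.7. In the adipose array 1 member was at least 2-fold higher (Tyrobp, 2.00-fold, 0.59 on the log2 scale with the span trend removed). Adgre1 read 39.4 units in the adipose array and 227 in the spleen array (-0.83 with values under the filter set to it), and Csf1r 114 and 473. B cell markers had a median of -0.87 (percentile 14.48 on level, 1.3 on level and span), with 3 of 6 at least 2-fold higher in the spleen array. These were Bank1 (5.11-fold), Ms4a1 (2.33-fold) and Cd79b (2.04-fold), and none was at least 2-fold higher in the adipose array. None of these kept a 2-fold difference under each setting. With values under the filter set to it, Bank1 differed by -0.30 and Ms4a1 by -0.65, and Cd79b differed by -0.64 after quantile normalization. MHC class II genes had a median of -0.91 (percentile 9.4 on level, 0.345 on level and span), with Cd74 3.03-fold and H2-Aa 2.95-fold higher in the spleen array. Adipocyte markers had a median of 0.54 (percentile 98.0 on level, 94.1 on level and span, and 92.7 with the level filter at 8). None of the 9 was at least 2-fold apart as deposited, and Cidec (1.82-fold), Plin4 (1.70-fold), Fabp4 (1.62-fold) and Retn (1.56-fold) were the furthest higher in the adipose array. After quantile normalization these 4 were at least 2-fold higher there. Stromal and endothelial markers had a median of 0.46 (percentile 96.4 on level, 99.8 on level and span) that was -0.68 with the level filter at 8, with Cav1 1.90-fold and Gsn 1.67-fold higher in the adipose array. After quantile normalization 2 stromal markers, and with the span trend removed 4, were at least 2-fold higher there. In that list Pecam1 (2.83-fold) and Dcn (2.66-fold) were higher in the spleen array, and differed by -0.62 and -0.69 with the span trend removed.

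Dendritic cell markers (3 members, median 0.37, percentile 76.3) and NK cell markers (4 members, median -0.40, percentile 41.4) did not stand apart. With the span trend removed these medians were -0.09 and 0.07. Fewer than 3 members passed the filter in the neutrophil list (Mmp9, 3.61-fold higher in the adipose array), the conventional CD8 T cell list (Themis), the list of type 2 innate lymphoid and mast cells (Gata3) and the erythroid and platelet list (none). Housekeeping genes had a median of -0.59 (percentile 5.2 on level, 2.3 on level and span), with 5 of 12 at least 2-fold higher in the spleen array and none in the adipose array. Hprt was 4.65-fold, Ywhaz 3.41-fold and Tbp 3.29-fold higher in the spleen array, whereas Actb and Rplp0, chosen after their values were seen, differed by -0.02 and -0.01, and by -0.17 and 0.14 after quantile normalization. Of the 26 lists with at least 3 members past the filter, 3 lay above and 7 below the range of random lists matched on level. When span was matched too, 3 lay above and 11 below.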

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

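Random lists matched on level and span and the removal of the span trend were chosen after the data were seen; the other settings were not. Over all of these settings, 292 of 337 list results kept their place inside or outside the random range, 11 of the 26 lists did so under every setting tried, and none went to the opposite side. Of these 11, only the immediate-early, NK receptor and NKT2 lists stood apart, and the others stayed inside the range. The immediate-early list stayed above all random lists (medians 0.87 to 1.45), and the NK receptor (-2.001 to -0.56) and NKT2 (-1.30 to -0.84) lists stayed below the range. For 115 named genes, 1108 of 1131 values under the settings fixed beforehand, and 98 of 115 with the span trend removed, kept their side of the 2-fold threshold. Level filters and the limit to genes with 1 probe set leave a gene's difference unchanged by construction. Many of these genes were also named for large differences in the same arrays, so the counts do not measure robustness. No gene at least 2-fold apart turned its direction. Itga2, under 2-fold apart, did so under quantile normalization, and Itga2, Bst2 and Pfkfb3 with the span trend removed. Low signal limits the folds: the spleen array lay under the filter in 160 genes of the adipose-higher count, and the adipose array in 1247 genes of the spleen-higher count. No paired analysis was possible because each tissue has 1 array. The causes of the movements below were not tested, apart from thresholds and filters, which change the genes counted by construction.

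The count of genes higher in the adipose array was 1704 at 1.5-fold, 53 at 4-fold, 1151 after quantile normalization and 952 with the span trend removed. The count higher in the spleen array was 669 at 4-fold and 1407 with the span trend removed. The correlation across genes, 0.65 as deposited, was 0.77 with a filter of 6, 0.54 with a filter of 8, 0.90 with no filter, 0.72 with the offset and 0.70 with low values set to the filter.

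Lists that left the outside of the random range had these medians. With a filter of 6 they were -0.085 for NKT17 and 0.29 for cell-cycle genes. With a filter of 8 they were -1.09 for circulation, 0.64 for adipocyte and -1.54 for macrophage genes. With no filter they were -0.57 for identity, -0.085 for NKT17, -0.59 for circulation and 0.23 for cell-cycle genes. With the offset they were -0.68 for NKT17 and 0.23 for cell-cycle genes. Cell-cycle genes also left it after loess on level (0.21) and quantile normalization (0.48). With low values set to the filter the identity list (-0.62) left it, and with only genes of 1 probe set the heat-shock list (-1.31, percentile 2.6). Against lists not matched on level the identity (-0.62) and adipocyte (0.54) lists left it. Against lists matched on level and span the identity (-0.62), cell-cycle (0.44) and adipocyte (0.54) lists left it. With the span trend removed the identity (-0.16), circulation (-0.12), cell-cycle (0.25) and adipocyte (0.42) lists left it.

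Other lists moved outside the range. With the offset these were cytokine (0.40) and interferon genes (-0.74). With a filter of 6 they were interferon (-0.85) and stromal genes (0.48), and with no filter interferon (-0.69), B cell (-0.48) and stromal genes (0.49). Low values set to the filter moved stromal genes (0.40), and only genes of 1 probe set moved housekeeping genes (-0.997). Lists matched on level and span moved the NKT1 (-0.38), lipid (0.28), interferon (-0.96), B cell (-0.87), MHC class II (-0.91), stromal (0.46) and housekeeping (-0.59) lists. Removal of the span trend moved interferon (-0.99), B cell (-0.97), MHC class II (-1.01), stromal (0.61) and housekeeping (-0.58) lists.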

Other observations

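The gene groups in the first paragraphs, the tests on gene span, on the share after quantile normalization and on macrophages in the spleen sort, and the test of a digestion response limited to immediate-early genes were chosen after the data were seen, while the tests on heat-shock genes, macrophages in the adipose sort, adipocytes with stromal cells, and level were set before. The bound that counts only genes already 2-fold apart as deposited was set after both counts were seen, and the comparison with shuffled spans after the share was seen. Span matching of the adipocyte and stromal lists was also added after the data were seen. Replication-dependent histone genes, whose messages lack a poly(A) tail, were higher in the adipose array. Of 21 past the filter, 17 were at least 2-fold higher there and 1 in the spleen array, with a median log2 difference of 1.46. With the span trend removed the median was 1.07, and the counts were 11 and 1. Of 40 small nucleolar RNA genes, 31 were at least 2-fold higher in the adipose array and none in the spleen array, with a median of 1.28 that was 0.36 with the span trend removed, where 6 were at least 2-fold higher. The calcium-binding S100a genes and annexin genes, 10 in all, had a median of 0.85, with 4 at least 2-fold higher in the adipose array, among them Anxa2 (7.25-fold) and S100a4 (5.82-fold). The inhibitory receptors Tigit (4.46-fold) and Ctla4 (3.21-fold) were also higher in the adipose array, both with the spleen array under the filter.

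3 gene families picked after the data were seen, and not set against random lists, were higher in the spleen array. All 6 Ifi200-family genes past the filter were at least 2-fold higher there (median -3.24), as were all 4 Trim30 and Trim12 genes (median -2.75) and 3 of 4 Slfn genes (median -1.81). These families hold similar copies that a probe set can share. These medians kept their sign under each scaling and with the span trend removed (-2.75, -2.27 and -1.95). Slc40a1, the iron exporter (8.90-fold), and Vcam1 (8.73-fold), both known from splenic red pulp macrophages, and the albumin gene Alb (8.90-fold) were higher in the spleen array, as was the fixed macrophage list (median -1.54). Cytosolic ribosomal protein genes, by contrast, had a median of -0.12 over 56 genes, with none at least 2-fold higher in the adipose array and 2 in the spleen array. Their median was 0.09 after quantile normalization, and -0.54 with the span trend removed, where 6 were at least 2-fold higher in the spleen array.

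The first pattern is the excess of genes higher in the spleen array. A narrower range of values in the adipose array does not account for the total count, since removal of the level trend left 2841 genes at least 2-fold apart against 2784 as deposited, but for the excess it stays open: the adipose-higher share of 2-fold genes went from 17.0% to 17.7% with the level trend removed and to 39.0% after quantile normalization. Loss of long-gene signal in the adipose array, through RNA quality, priming or amplification, stays open: the difference fell along gene span with a rho of -0.48 (-0.45 to -0.52 within bands of level, -0.47 after quantile normalization), but with 1 array per tissue this cannot be told apart from a tissue difference that follows gene span, and the share of 40.4% with the trend removed decides nothing, since the same removal with spans shuffled among genes gave 38.2%. Whether it is the whole cause of the 2-fold differences stays open, since 2359 genes were at least 2-fold apart with the trend removed but only 1554 of these had been so as deposited. With spans shuffled among genes, the same removal left 2901 genes at least 2-fold apart, of which 2263 had been so as deposited (means of 20 shuffles). Both counts were thus lower with the true spans, while part of the loss of deposited genes came without them. The tissue difference was not tested, and transcript length was not used here.

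The second pattern is the immediate-early list. Its short genes are not the whole cause, because its median stayed at 0.87 with the span trend removed and above all random lists matched on span. A general stress response to collagenase digestion was predicted to raise the heat-shock list in the adipose array, which was not seen. That list lay at percentile 0 among lists matched on level and span. With only genes of 1 probe set it lay at 2.6, inside the random range but on the spleen side. This does not decide against such a response, since digestion and tissue fall on the same array. The housekeeping list was low as well, at percentile 2.3 on level and span. Inducible heat-shock members, chosen after their values were seen, went both ways (Dnajb1 0.73, Bag3 0.68, Hspa1a -0.14 and Hsph1 -1.31 on the log2 scale). A digestion response limited to immediate-early genes cannot be told apart from the tissue, since only adipose tissue was digested, and the immediate-early list lay at percentile 100. Stimulation of iNKT cells within adipose tissue may therefore be the source as well, and was not tested.

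The third pattern is carry-over of other cells, which the gate on CD45, TCR beta and tetramer and the second sort would remove in large part. Carry-over of macrophages in the adipose sort was predicted to raise 5 abundant macrophage transcripts there (Lyz2, C1qa, C1qb, Apoe and Ctss). This was not seen, as 0 of 5 were higher in the adipose array. Whether the adipose sort held macrophages cannot be told from this, since larger carry-over in the spleen sort would give the same. Of 12 macrophage markers past the filter, 6 reached it in the adipose array and 12 in the spleen array. Carry-over of macrophages in the spleen sort stays open, although all 5 were higher there (C1qb read 273 units in the adipose array and 820 in the spleen array). The 5 belong to the list that raised the question, and expression by the iNKT cells themselves, which was not tested, would give the same. With the level filter at 8 the list kept a median of -1.54 but lay inside the random range (percentile 10.7). Carry-over of adipocytes or stromal cells in the adipose sort stays open: the adipocyte list lay at percentile 98.0 among lists matched on level but at 94.1 with span matched, while the stromal list lay at 96.4 and 99.8. No member of either was at least 2-fold higher in the adipose array as deposited, but 4 of 9 adipocyte and 2 of 10 stromal markers were after quantile normalization, and 0 and 4 with the span trend removed, and 6 of 9 and 9 of 10 reached the filter in the spleen array too.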
